A study of Mus musculus with 9 samples.

How the data were processed

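RNA was sequenced from the sensory epithelium of the mouse utricle, one of the gravity-sensing organs of the inner ear, at embryonic day 17.5 (E17.5), on the day of birth (P0) and at postnatal day 9 (P9). The strain was Swiss Webster and each age had 3 libraries, 9 in all. Per the labels, sensory epithelia were isolated from removed utricles, RNA was extracted with a Qiagen RNeasy Micro kit, and libraries were made from total RNA with Illumina protocols. The labels do not say whether the 3 libraries of an age came from separate animals or pools, so p-values measure the spread between these libraries, which may be technical.

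The deposited expression table held RPKM values, read counts scaled to gene length and library size, computed by the authors. The submitters' processing notes list the mm8 build and the Partek software with no version. The aligner, the gene annotation and the counting rule, strand included, are not given in the sources used here. Tested on the table itself, each of the 10102 genes reached 5 RPKM in at least 1 library, so genes below that floor throughout were not measured here. Per the file header, libraries held between 53365510 and 64417934 alignments. The gene lengths behind the values are not given in the sources used here, so whether the values imply whole reads was not tested. With GENCODE vM21 lengths, 3 of 89745 values above 0 implied under 0.5 reads. No count-based test was run, since RPKM values are not counts. Of 18 symbols that a spreadsheet had turned into dates, 4 could be restored by matching values between the tables.

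The authors' deposited table for E17.5 against P9 gave a ratio of mean RPKM, a signed fold score and p-values for 1967 genes. A 1-way analysis of variance on untransformed RPKM was fitted over the 3 ages, and its contrast of E17.5 with P9 was tested. A Benjamini-Hochberg adjusted p of that contrast under 0.05 and a ratio of at least 2 in either direction returned the same 1967 genes. The ratio and p-values in the authors' deposited table of transcription factors covered 104 genes, all of them among the 1967. The last line of that table belonged to another gene and was left out.

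Values were analysed as log2(RPKM + 1), a scale that understates the change of genes with low values. One linear model with a mean per age was fitted to all 9 libraries in limma 3.58.1 (R 4.3.3), with an intensity trend in the empirical Bayes step. The contrasts were P9 minus E17.5, P0 minus E17.5, P9 minus P0, and the change from P0 to P9 minus the change from E17.5 to P0, called the interval contrast. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 10102 genes were called. An exact permutation test of 3 against 3 libraries cannot go below 0.10, so the moderated test was used. Levels are mean RPKM ± SD over 3 libraries, and log2 fold changes carry the standard error of the fit.

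Before the data were examined, 32 gene lists were fixed, covering hair cells, supporting cells, signalling pathways, the cell cycle and other cell types, and 31 of them had measured members. None of the endothelium markers were in the table, which excludes nothing. Since each gene reached 5 RPKM in at least 1 library, members below that at an age entered through another age. Counts of changed members therefore depend in part on this floor. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 31 lists within a contrast. Named genes followed a fixed rule. It took the 10 largest rises and falls from E17.5 to P9, 5 each way for the other pairs of ages and for the transcription factor table, the 4 members of each list with the smallest p, and 6 regulators chosen in advance. The largest changes had to be called, to reach a mean of 5 RPKM at 1 of the ages and to have every library of one age above every library of the other. Symbols of predicted or unnamed genes were skipped. Further list members are named below to complete a list's description, and those were chosen after their values were seen. Some genes that the rule names are not reported here.

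The procedure was tested on simulated data with the means and spread of the 10102 genes and 200 changed genes. For P9 against E17.5, 71.6% of genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 13 false calls. For P0 against E17.5 the shares were 64.2%, 97% and 97% with 10 false calls, and for P9 against P0 77.6%, 94% and 100% with 14 false calls. Simulated data with no change gave 0 calls in each contrast and 0 of 31 lists. The simulated genes were drawn independently, while the estimated correlation within the real lists reached 0.886 for ribosomal protein genes. The simulation therefore does not test how often camera with the preset correlation calls a correlated list falsely. On the real values, 7046 genes had an unadjusted p under 0.05 for P9 against E17.5.

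Alternatives were other pseudocounts, a minimum mean of 10 RPKM, quantile normalization, trimmed-mean scaling, a fit of only the 2 ages compared, the sample number as a block, empirical Bayes settings, a fold minimum, and removal of each library. The empirical Bayes settings do not enter camera, so for lists they repeated the main test and could not change a call. They are included where alternatives for lists are counted below. Merging of repeated symbols was not needed, since no symbol was repeated. Transcript length, GC content and gene overlaps came from GENCODE vM21, which is on another build than the one the submitters list, so no coordinates are given. Length and GC content were those of the longest annotated transcript of each gene. Some alternatives were added after seeing the data. These were removal of a trend on length and GC content from the fold changes of ribosomal protein genes, a second way to count their length-matched genes, and counts of genes that changed direction. Other pseudocounts and ratios of mean RPKM for the interval contrast, quartiles of marker lists limited by level, and the alternatives for lists in contrasts other than P9 minus E17.5, were also added then. Exons of 39 of the 142 named genes overlapped another annotated gene there, and for 12 the partner was in the table. Of these, 9 had a partner called in their own direction for P9 against E17.5. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.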

Results

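The series measured gene expression in the sensory epithelium of the utricle in Swiss Webster mice at E17.5, P0 and P9, with 3 libraries per age. This epithelium holds hair cells, which detect head movement through a bundle of actin-filled stereocilia, and the supporting cells around them. Libraries held 53365510 to 64417934 alignments, and the table gave RPKM for 10102 genes. Ribosomal protein genes took 9.27% to 10.96% of summed RPKM in the 6 libraries of E17.5 and P0 and 5.25% to 5.36% in the 3 libraries of P9. Mitochondrial genes took 11.3% to 16.0%, with P9 replicate 2 at 15.9% and the other P9 libraries at 11.6% and 11.3%.

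Libraries grouped by age. On log2 values, the first principal component held 79.1% of the variance and ran from E17.5 through P0 to P9, and the second held 7.81% and set P0 apart. Correlations across genes, which are not independent replicates, were 0.988 to 0.989 within E17.5, 0.984 to 0.992 within P0 and 0.977 to 0.988 within P9. Between ages they were 0.953 to 0.964 for E17.5 with P0, 0.889 to 0.908 for P0 with P9 and 0.810 to 0.827 for E17.5 with P9.

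**Figure D1:**
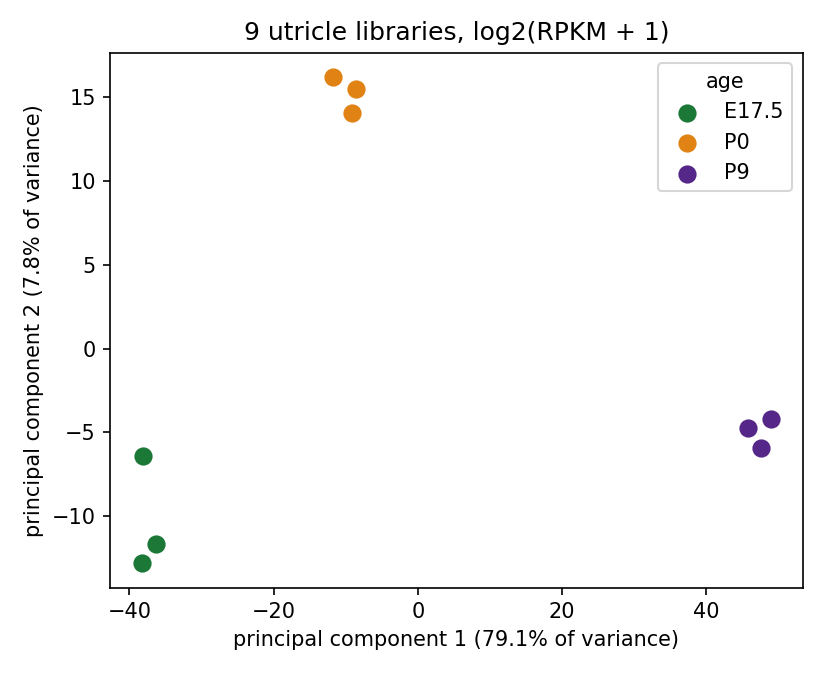
Principal components of log2(RPKM + 1) over 10102 genes, component 1 on the horizontal axis and component 2 on the vertical axis, with 1 point per library coloured by age. The 3 libraries of each age sit together, and component 1 holds 79.1% of the variance.

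The comparison of E17.5 with P9, the one that the study tabulated, asks which genes change as the utricle matures. The embryonic gene Dlk1, a Notch-related membrane protein, fell from 59.2 ± 9.04 to 0.194 ± 0.031 RPKM (log2 fold change -5.65 ± 0.13, adjusted p = 7.9e-11, limma). Among the other 9 largest falls were the dividing-cell genes Top2a, Cdk1 and Ube2c and Oc90, the main matrix protein of otoconia, which went from 1367 ± 60.2 to 91.2 ± 3.17 RPKM. The tight junction genes Cldn24 and Cldn22 fell by 5.17 ± 0.19 and 4.96 ± 0.17 on the log2 scale. The chemokine gene Ccl21c, the matrix gene Fbln1 and the chloride channel gene Ano1 fell by 3.92 ± 0.24, 3.61 ± 0.10 and 3.51 ± 0.10 on the log2 scale. Exons of Cldn22 overlap those of Wwc2 on the opposite strand, and Wwc2 had 13.8 RPKM at E17.5 and 14.3 RPKM at P9 (adjusted p = 0.578). Ccl21c has near-identical copies, so the reads of both genes are uncertain.

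On the log2(RPKM + 1) scale the largest rise from E17.5 to P9 was that of Ighm, the immunoglobulin mu heavy chain, from 0.483 ± 0.4 to 158 ± 122 RPKM (log2 fold change 6.51 ± 0.41, adjusted p = 8.37e-08). The P9 libraries held 298, 90.8 and 83.6 RPKM of Ighm, all above the E17.5 libraries. The metallothionein genes Mt2 and Mt1, which encode metal-binding proteins, rose by 5.43 ± 0.19 and 4.66 ± 0.14 on the log2 scale, and the antioxidant enzyme genes Gpx2 and Sod3 by 4.76 ± 0.57 and 4.47 ± 0.12. Tspan8, a tetraspanin gene, went from 5.93 ± 0.31 to 208 ± 33.6 RPKM, and the long noncoding RNA Neat1 from 3.89 ± 0.98 to 123 ± 22.6 RPKM. The other large rises were Igfbp6 at 4.82 ± 0.13, Ptx3 at 4.42 ± 0.17 and the stress-response gene Nupr1, from 0.639 ± 0.094 to 37.6 ± 13.5 RPKM. Over all genes, limma called 3116 higher and 3692 lower at P9, of which 945 and 773 changed at least 2-fold on the fitted scale.

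Genes of cell division fell together between E17.5 and P9. Of 55 measured members of the cell cycle list, 52 fell and 1 rose, with the same counts when adjusted over the list alone, and the median log2 fold change was -2.30, or -1.32 with a pseudocount of 5. The list was lower than other genes (camera adjusted p = 1.4e-20), but not so with its correlation estimated, adjusted p = 0.151 with an estimated correlation. Top2a, which untangles replicating DNA, went from 25.5 ± 1.71 to 0.518 ± 0.118 RPKM, Cdk1 from 25.1 ± 2.98 to 0.52 ± 0.363, and Ccnd1, the G1 cyclin D1, from 94.9 ± 2.77 to 8.37 ± 1.22. The mitotic genes Ccna2 and Prc1 fell by 3.43 ± 0.11 and 3.18 ± 0.10, and Ube2c fell by 3.94 ± 0.18. Exons of Ccna2 and Prc1 overlap those of Exosc9 and Rccd1 on the opposite strand, so their reads are uncertain. Bub3 was the member that rose, by 0.24 ± 0.10. Of 6 genes for cyclin-dependent kinase inhibitors and the Rb family, 3 rose and 1 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.51). The imprinted inhibitor gene Cdkn1c fell by 1.30 ± 0.11 while Cdkn2d, Cdkn1b and Cdkn1a rose by 0.68 ± 0.12, 0.37 ± 0.10 and 0.53 ± 0.15.

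Imprinted and fetal growth genes fell as well, 16 of 20 against 2 that rose, with the same counts adjusted over the list alone and a median of -1.50 (camera adjusted p = 2.04e-05; adjusted p = 0.149 with an estimated correlation). Besides Dlk1, the imprinted gene Nnat went from 61.3 ± 1.71 to 6.45 ± 0.332 RPKM, the RNA-binding protein gene Igf2bp3 from 13.8 ± 1.5 to 2.11 ± 0.168, and the chromatin protein gene Hmga2 from 12.9 ± 1.21 to 0.688 ± 0.093. Of 39 chromatin regulators, 25 fell and 5 rose, again the same adjusted over the list alone, with a median of -0.50 (camera adjusted p = 6.64e-04; adjusted p = 0.151 with an estimated correlation). Among them Uhrf1, which maintains DNA methylation at replication, fell by 2.38 ± 0.09, the Polycomb gene Cbx2 by 2.60 ± 0.16 and the histone methyltransferase gene Ezh2 by 1.32 ± 0.07. Of 74 ribosomal protein genes 73 fell and 0 rose, with the same counts adjusted over the list alone and a median of -1.04 (camera adjusted p = 7.22e-14; adjusted p = 0.565 with an estimated correlation). Rps26 went from 982 ± 75.5 to 289 ± 25.4 RPKM and Rps19 from 511 ± 38.4 to 169 ± 3.67 RPKM. Rps24 fell by 1.52 ± 0.13, and Rps28 went from 706 ± 67.2 to 249 ± 23.5 RPKM. Ribosomal protein genes have many processed pseudogenes, so the counting could split their reads. The 60 measured genes of oxidative phosphorylation did not move as a group (5 higher, 8 lower, median -0.09, camera adjusted p = 0.785), and 2 and 2 were called when adjusted over the list alone. Among them Ndufa10 and Atp5g2 fell by 0.53 ± 0.10 and 0.62 ± 0.12 and Ndufb10 and Cox6a1 rose by 0.54 ± 0.13 and 0.46 ± 0.11.

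The 3 SoxC transcription factor genes, which act in progenitors and newly formed cells, all fell from E17.5 to P9, both over all genes and adjusted over the list alone (3 of 3, median -1.16, camera adjusted p = 0.0325; adjusted p = 0.464 with an estimated correlation). Sox11 went from 10.01 ± 2.1 to 0.97 ± 0.199 RPKM (log2 fold change -2.47 ± 0.14), and Sox4 from 114 ± 6.41 to 50.3 ± 4.38 RPKM (-1.16 ± 0.09). Sox12 went from 24.0 ± 2.02 to 14.1 ± 2.08 RPKM (-0.74 ± 0.10). With genes limited to a mean of 10 RPKM, which leaves out Sox11, the list was no longer called (adjusted p = 0.125), and over 18 alternatives with the preset correlation its adjusted p ran from 0.0216 to that value.

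Most bundle genes of the hair cell rose, while its fate regulators were split. RNA came from the whole epithelium, so a changed share of hair cells cannot be told apart from changed expression within them. The same limit holds for the hair cell synapse genes below. Of 18 regulators, 10 fell and 4 rose, the same adjusted over the list alone, with a median of -0.38, and the list as a whole did not pass (camera adjusted p = 0.107). Atoh1, which is required for hair cell formation, fell from 34.5 ± 2.57 to 13.7 ± 1.26 RPKM (adjusted p = 3.72e-07), and Dll3, Hes6 and Isl1 fell by 1.83 ± 0.12, 1.59 ± 0.11 and 0.85 ± 0.10. Pou4f3, a survival factor of hair cells, had 85.6 ± 8.28 and 86.2 ± 2.98 RPKM (adjusted p = 0.896), and Gfi1 rose from 64.1 ± 3.43 to 80.3 ± 3.18 RPKM (adjusted p = 0.00473). Exons of Gfi1 overlap those of a gene on the opposite strand, so its reads are uncertain. Among 42 hair bundle and transduction genes, 28 rose and 7 fell, the same adjusted over the list alone, with a median of 0.64 (camera adjusted p = 2.61e-04; adjusted p = 0.368 with an estimated correlation). The transduction channel gene Tmc1 went from 1.79 ± 0.044 to 16.0 ± 1.19 RPKM, Dfnb59, the gene of pejvakin, from 10.8 ± 1.37 to 68.8 ± 12.7 RPKM. The bundle calcium pump gene Atp2b2 went from 12.2 ± 0.11 to 45.2 ± 4.14 RPKM and the actin-bundling gene Espn from 60.7 ± 1.69 to 189 ± 8.02 RPKM. Among those that fell were Pls3, Whrn, Pcdh15, Gpr98, Grxcr1 and Myo6.

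Synapse, channel and calcium-binding genes of hair cells rose in 20 of 27 cases and fell in 3, or 20 and 4 adjusted over the list alone, with a median of 0.66 (camera adjusted p = 2.66e-05; adjusted p = 0.363 with an estimated correlation). The potassium channel gene Kcna10 rose from 24.6 ± 2.4 to 128 ± 16.5 RPKM. The calcium-binding gene Cabp2 rose from 71.5 ± 2.5 to 274 ± 32.6 RPKM and Kcnab1 from 3.40 ± 0.064 to 21.1 ± 2.06 RPKM. Neuron markers moved in the same direction, with 7 of 10 higher and 1 lower, the same adjusted over the list alone, and a median of 0.59 (camera adjusted p = 0.0155; adjusted p = 0.492 with an estimated correlation). Ntrk2, Mapt and Rbfox3 rose by 2.25 ± 0.11, 2.19 ± 0.13 and 1.58 ± 0.11, and Uchl1 fell by 2.47 ± 0.12. Among genes with a mean of at least 10 RPKM the neuron list was not called, with a median of 0.13 and adjusted p = 0.658, the highest of 18 alternatives with the preset correlation, of which the lowest was 0.0111.

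Supporting cell and prosensory genes split, with 10 of 26 higher and 12 lower, also when adjusted over the list alone (camera adjusted p = 0.927, median -0.19, mean 0.00). The gap junction gene Gjb6 rose from 8.83 ± 0.683 to 60.5 ± 15.8 RPKM and the transporter gene Slc6a14 from 13.6 ± 1.04 to 84.2 ± 5.75 RPKM. Lgr5, a Wnt target that marks inner ear progenitors, fell from 30.8 ± 2.97 to 6.46 ± 1.18 RPKM and the Notch effector gene Hey1 from 33.4 ± 3.24 to 6.16 ± 0.944 RPKM. In the Notch pathway 17 of 30 genes fell and 4 rose, the same adjusted over the list alone (median -0.42, camera adjusted p = 0.0751). Among them the ligand gene Jag1 fell by 1.84 ± 0.13 and the modifier gene Mfng fell by 1.26 ± 0.08. In the Wnt pathway 20 of 40 fell and 11 rose, or 21 and 11 adjusted over the list alone (median -0.26, camera adjusted p = 0.235). Dkk2, Lgr4 and Fzd3 had log2 fold changes of -2.35 ± 0.12, -1.34 ± 0.08 and -1.48 ± 0.11. Of 27 Hippo pathway genes 14 fell and 6 rose, the same adjusted over the list alone (median -0.23, camera adjusted p = 0.411). Tead2 and Vgll3 fell by 3.10 ± 0.13 and 1.59 ± 0.14, and Tead4 and Crim1 rose by 1.61 ± 0.15 and 1.13 ± 0.09. Among 39 inner ear transcription factor genes, 23 fell and 10 rose, the same adjusted over the list alone (median -0.52, camera adjusted p = 0.0816). Sall3, Mycn, Mycl1 and Tcf3 had log2 fold changes of -1.13 ± 0.08, -1.65 ± 0.14, -1.59 ± 0.14 and -1.15 ± 0.10. Without P9 replicate 3 the Notch and ear factor lists were called, both at adjusted p = 0.0408, the lowest of 18 alternatives with the preset correlation that reached 0.203 and 0.125. Exons of Crim1 overlap those of Fez2 on the opposite strand, so its reads are uncertain.

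Genes of the otoconia and the gelatinous membrane over the epithelium mostly rose: 13 of 20 rose and 3 fell, the same adjusted over the list alone, with a median of 0.65 (camera adjusted p = 0.0285; adjusted p = 0.565 with an estimated correlation). Of the 20 members 6 are also in another list, among them Car2 and Slc26a4 in the dark cell list and Atp2b2 in the bundle list. The rise of this list is therefore not independent of those. The carbonic anhydrase gene Car2 rose by 2.16 ± 0.10. Oc90 fell by 3.89 ± 0.11, Fgf3 fell by 2.12 ± 0.11 and Otop1 fell by 1.35.

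**Figure D2:**
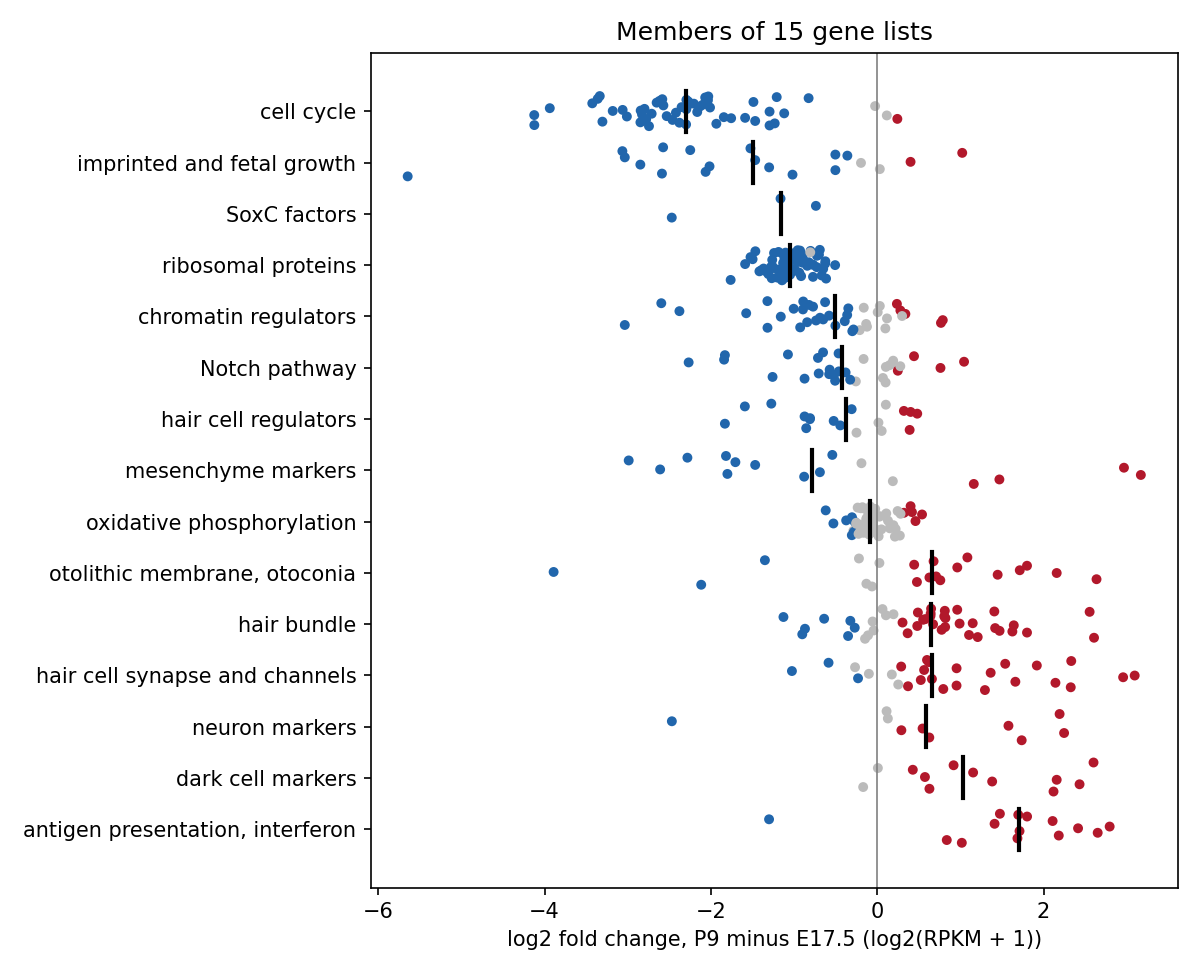
Log2 fold change from E17.5 to P9 on the log2(RPKM + 1) scale (horizontal axis) for the members of 15 gene lists (vertical axis). Each point is 1 gene, red where called higher, blue where called lower and grey where not called, with no meaning in its height within a list. The black bar is the list's median, which ran from -2.30 for the cell cycle to 1.70 for antigen presentation and interferon genes.

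Markers of other cell types changed with age in both directions. Dark cell markers, the ion transport genes of the neighbouring potassium-secreting epithelium, rose in 10 of 12 cases and 0 fell, the same adjusted over the list alone, with a median of 1.04 (camera adjusted p = 2.85e-04; adjusted p = 0.368 with an estimated correlation). The 6 of them with a mean of at least 10 RPKM had a median of 1.64. Of these, the sodium pump subunit genes Atp1b2 and Atp1b1 rose from 36.8 ± 1.04 to 203 ± 13.3 and from 70.9 ± 6.3 to 311 ± 9.71 RPKM. Atp1b1 is broadly expressed, and its exons overlap those of Nme7 on the opposite strand. The potassium channel gene Kcne1 rose from 2.84 ± 0.792 to 22.1 ± 2.31 RPKM. Mesenchyme markers fell in 10 of 16 cases and rose in 4, the same adjusted over the list alone, with a median of -0.78 (camera adjusted p = 0.163). The 4 with a mean of at least 10 RPKM, a limit that Bgn and Car3 passed because they rose and Dcn missed because it fell, had a median of 1.39. Mfap4 and Dcn fell by 2.99 ± 0.12 and 2.28 ± 0.11, while Bgn and Car3 rose by 3.17 ± 0.14 and 2.97 ± 0.16. Schwann cell and myelin markers rose in 6 of 11 cases and fell in 2, the same adjusted over the list alone (median 0.98, camera adjusted p = 0.0751). Mal, Gldn, Pllp and S100b rose by 2.53 ± 0.11, 2.87 ± 0.13, 1.98 ± 0.15 and 1.57 ± 0.16. Of 4 melanocyte markers 3 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0751). Pmel, Kcnj10 and Kit rose by 1.68 ± 0.11, 1.24 ± 0.11 and 0.54 ± 0.08, and Ednrb had 10.1 ± 2.03 and 9.14 ± 1.7 RPKM. Without P9 replicate 3 the Schwann cell and melanocyte lists were called, both at adjusted p = 0.0479, the lowest of 18 alternatives with the preset correlation that reached 0.537. Exons of Pmel overlap those of Dgka, which rose by 2.15, and Cdk2, which fell by 1.12, on the opposite strand. Those of Mfap4 overlap exons of Mapk7 on the opposite strand, which fell by 0.65. The reads of Pmel and Mfap4 are therefore uncertain.

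Of the fixed list of macrophage and other leukocyte markers only Cd68 was measured, while Ighm, described above, is an immunoglobulin gene outside that list. Cd68 rose from 1.83 ± 0.502 to 5.53 ± 1.37 RPKM (camera adjusted p = 0.336 for this list of 1, which was also called adjusted over the list alone). Of 4 erythroid genes, 1 was called higher, Fech by 0.51 ± 0.09, both over all genes and adjusted over the list alone (camera adjusted p = 0.698, with a median of -0.23 against a test direction of higher). Tfrc had 8.96 ± 0.665 and 10.3 ± 0.809 RPKM. The globin genes Hba-a1 and Hbb-b1, which have near-identical copies, had 29.0 ± 11.1 and 22.7 ± 8.16 RPKM at E17.5 and 20.8 ± 19.4 and 17.2 ± 15.3 RPKM at P9. P9 replicate 2 held 43.2 RPKM of Hba-a1 against 9.76 and 9.48, and without it both globin genes were called lower, at adjusted p = 0.00828 and 0.00813, the lowest over 19 alternatives that reached 0.544 and 0.638. Of the 2 measured muscle genes, Actc1 fell by 3.17 ± 0.11 and Pvalb, also a calcium buffer of hair cells, rose by 0.56 ± 0.10, both also called adjusted over the list alone (camera adjusted p = 0.698).

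Genes of antigen presentation and the interferon response rose in 13 of 14 cases and fell in 1, the same adjusted over the list alone, with a median of 1.70, or 1.03 with a pseudocount of 5 (camera adjusted p = 2.04e-05; adjusted p = 0.111 with an estimated correlation). Ifi35 rose from 1.90 ± 0.215 to 19.3 ± 3.49 RPKM, and the peptide transporter gene Tap2 from 0.376 ± 0.102 to 6.35 ± 0.817 RPKM. Lgals3bp rose from 1.47 ± 0.129 to 7.03 ± 0.905 RPKM. Of 34 listed genes these 14 were measured, since the table holds only genes that reached 5 RPKM in at least 1 library. Tap2 and Lgals3bp were below that floor at E17.5 and entered through a later age. The share that rose and the median therefore depend in part on the floor. With genes limited to a mean of 10 RPKM the call ended, at adjusted p = 0.0568, the highest of 18 alternatives with the preset correlation, of which the lowest was 1.02e-05. Immediate early and heat shock genes split into 12 higher and 12 lower of 28, or 12 and 13 adjusted over the list alone (camera adjusted p = 0.533, median -0.21, mean 0.40). Hspb1 went from 14.7 ± 2.43 to 230 ± 35.1 RPKM and Hsph1 from 31.5 ± 3.21 to 112 ± 9.32 RPKM. Hspa1b and Hspa1a, a near-identical pair whose reads are uncertain, rose by 4.23 ± 0.22 and 4.05 ± 0.25.

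The study also listed transcription factors that differed between E17.5 and P9. The authors' deposited table held 104, of which 58 were higher at E17.5 and 46 lower. In the limma fit 58 of these fell and 46 rose, both over all genes and adjusted over the list alone. The list was chosen by the study on these samples and is not independent evidence of direction. The largest falls were those of Tead2, a partner of YAP, from 63.5 ± 5.86 to 6.58 ± 1.38 RPKM, of the chromatin protein gene Hmgb2 from 50.7 ± 3.26 to 5.46 ± 0.929 RPKM, of Lbx2, of Sox11 and of Hey1. Lbx2 fell by 2.70 ± 0.10. The largest rises were those of Nr1d1, a repressor of the circadian clock, from 3.64 ± 0.404 to 49.3 ± 10.1 RPKM, and of 4 others. These were Bcl3 by 3.38 ± 0.21, Stat5a by 2.81 ± 0.12, Cebpd by 2.72 ± 0.35 and the clock-controlled gene Dbp by 2.53 ± 0.13. Exons of Nr1d1, Stat5a and Dbp overlap those of Thra, Stat3 and Sphk2 on the opposite strand, and these partners rose by 0.59, 0.41 and 0.58, so the reads of all are uncertain.

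**Figure D3:**
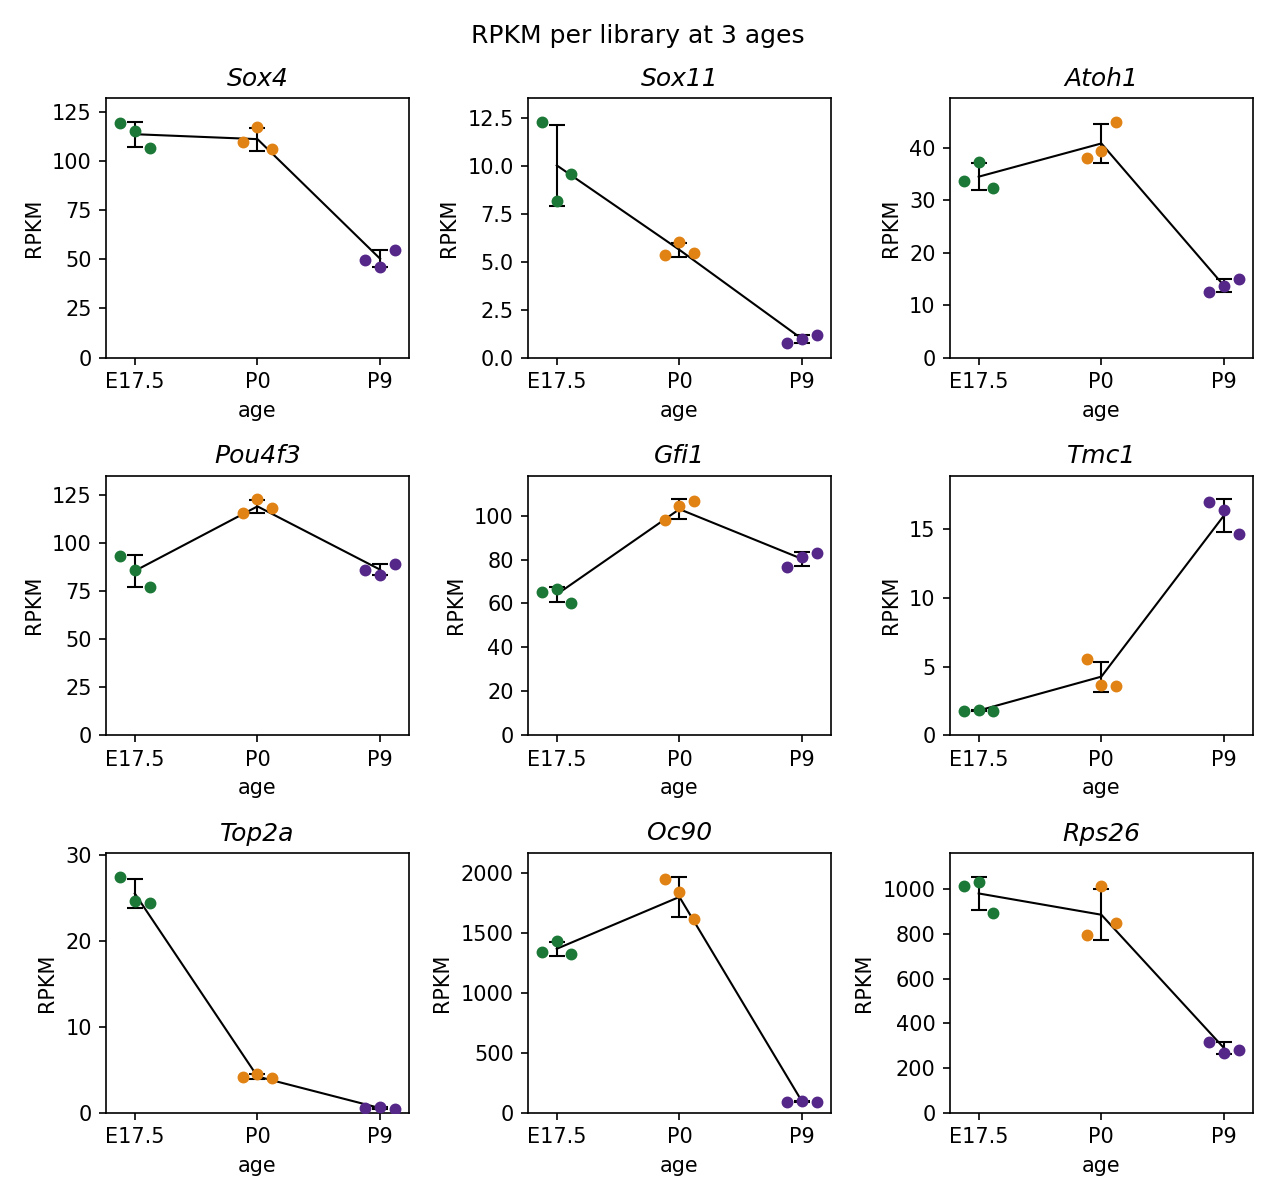
RPKM (vertical axes, starting at 0) of 9 genes at E17.5, P0 and P9 (horizontal axes), with 1 point per library and a black line through the means with SD bars (n = 3). Sox4 had 114 RPKM at E17.5, 111 RPKM at P0 and 50.3 RPKM at P9, while Top2a was at 4.19 RPKM by P0.

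Between E17.5 and P0, which asks what changes around birth, most genes of the cell cycle list fell. Of the 42 bundle genes, 21 rose, 1 fell and 20 were not called. Top2a dropped from 25.5 ± 1.71 to 4.19 ± 0.242 RPKM (log2 fold change -2.35 ± 0.10, adjusted p = 2.48e-07), and Cdk1 and Ube2c fell by 1.98 ± 0.16 and 2.17 ± 0.18. Of the 55 cell cycle genes 52 fell and 0 rose, the same adjusted over the list alone, with a median of -1.39 (camera adjusted p = 1.01e-38; adjusted p = 0.0813 with an estimated correlation). Dlk1 reached 12.3 ± 2.12 RPKM and the inner ear gene Otor fell from 11.4 ± 3.01 to 1.98 ± 0.976 RPKM. Ighm rose to 21.7 ± 7.3 RPKM, Fndc7 from 2.99 ± 0.38 to 22.2 ± 2.9 RPKM, and the matrix protein gene Spp1 from 102 ± 19 to 522 ± 77.5 RPKM. The rises of Gpx2 and Sod3 were 2.53 ± 0.57 and 2.16 ± 0.12. As a list the bundle genes were higher, with 22 and 1 called when adjusted over the list alone (camera adjusted p = 3.16e-07; adjusted p = 0.144 with an estimated correlation). Of the hair cell synapse and channel genes 19 rose and 0 fell, or 20 and 1 adjusted over the list alone (camera adjusted p = 1.45e-09; adjusted p = 0.121 with an estimated correlation). The 18 hair cell regulators were not called as a list, with 6 higher and 2 lower, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.169). Neuron markers rose alongside, 7 of 10 against 1 lower, or 9 and 1 adjusted over the list alone (camera adjusted p = 1.77e-04; adjusted p = 0.262 with an estimated correlation). Mesenchyme markers fell in 9 of 16 cases and rose in 3, the same adjusted over the list alone (camera adjusted p = 0.00681; adjusted p = 0.609 with an estimated correlation). Dark cell markers rose in 6 of 12 cases and fell in 1, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.539 with an estimated correlation). Schwann cell and myelin markers rose in 6 of 11 cases, or 7 adjusted over the list alone, and 0 fell (camera adjusted p = 0.0363; adjusted p = 0.262 with an estimated correlation). Melanocyte markers rose in 3 of 4 cases, or 4 adjusted over the list alone, and 0 fell (camera adjusted p = 0.0163; adjusted p = 0.285 with an estimated correlation). Cartilage and bone genes rose in 6 of 10 cases and fell in 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0163; adjusted p = 0.663 with an estimated correlation). Of the otolithic genes 13 of 20 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 1.77e-04; adjusted p = 0.319 with an estimated correlation). Interferon genes rose in 7 of 14 cases and 0 fell, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.00503; adjusted p = 0.121 with an estimated correlation). Fetal growth genes fell in 12 of 20 cases and rose in 1, or 13 and 1 adjusted over the list alone (camera adjusted p = 6.43e-07; adjusted p = 0.0813 with an estimated correlation). Chromatin regulators fell in 15 of 39 cases and 0 rose, the same adjusted over the list alone (camera adjusted p = 1.77e-04; adjusted p = 0.121 with an estimated correlation). Stress genes fell in 12 of 28 cases and rose in 2, the same adjusted over the list alone (camera adjusted p = 0.0149; adjusted p = 0.735 with an estimated correlation). Over 18 alternatives with the preset correlation, 6 of the 14 called lists kept their call throughout, though the empirical Bayes settings among them could not change it. These were the cell cycle, bundle, hair cell synapse, otolithic, fetal growth and chromatin lists. The Schwann cell list lost its call under 5 of them, with adjusted p from 0.0194 to 0.424, and the interferon list under 2, from 0.0025 to 0.0966. The neuron, mesenchyme, melanocyte, cartilage and bone, dark cell and stress lists each lost it under 1, at adjusted p = 0.0871, 0.819, 0.198, 0.0705, 0.0529 and 0.0537. Other lists were called only under some of the alternatives. Ribosomal protein genes (adjusted p = 0.295) were called lower under 3, at adjusted p as low as 1.61e-05 without P0 replicate 2, where oxidative phosphorylation (adjusted p = 0.455) was called lower at 0.00229. Cholesterol synthesis (adjusted p = 0.0563) was called higher under 6, the lowest at 0.0203, and the Hippo list (adjusted p = 0.0886) lower under 1, at 0.0241. The highest adjusted p of these 4 lists were 0.922, 0.984, 0.142 and 0.242. Overall counts were 1557 higher and 1362 lower at P0, with 129 and 100 changed at least 2-fold. The lower count fell to 820 without E17.5 replicate 2 and to 860 without P0 replicate 3.

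From P0 to P9, over the early postnatal days, the claudin genes Cldn24 and Cldn22 went from 41.3 ± 10.7 and 78.3 ± 19 RPKM to 0.322 ± 0.214 and 1.48 ± 0.19 RPKM (log2 fold changes -4.98 ± 0.19 and -4.98 ± 0.17). Oc90 dropped from 1800 ± 170 to 91.2 ± 3.17 RPKM (adjusted p = 6.07e-10). The microfibril gene Mfap2 fell from 317 ± 31.3 to 25.9 ± 3.33 RPKM, and Dlk1 fell by 3.47 ± 0.13. The largest rises were those of Cyp2g1, from 0.183 ± 0.091 to 21.8 ± 7.59 RPKM, Neat1 by 4.18 ± 0.17, Mt2 by 3.99 ± 0.19, Steap4 by 3.97 ± 0.16 and Hspa1b by 3.90 ± 0.22. Atoh1 fell from 40.8 ± 3.66 to 13.7 ± 1.26 RPKM (adjusted p = 2.71e-07). Of the 18 hair cell regulators 12 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.00137; adjusted p = 0.443 with an estimated correlation). Each of the 3 SoxC genes fell, also adjusted over the list alone (camera adjusted p = 0.0147; adjusted p = 0.464 with an estimated correlation), and Sox4 fell by 1.13 ± 0.09. Ribosomal protein genes fell in 73 of 74 cases, or 74 adjusted over the list alone, with a median of -0.996 (camera adjusted p = 5.68e-19; adjusted p = 0.512 with an estimated correlation). Interferon and antigen presentation genes rose in 12 of 14 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 5.94e-06; adjusted p = 0.0822 with an estimated correlation). Dark cell markers rose in 10 of 12 with 0 lower, the same adjusted over the list alone (camera adjusted p = 6.12e-05; adjusted p = 0.44 with an estimated correlation). Cell cycle genes went on falling, in 49 of 55 cases against 1 that rose, the same adjusted over the list alone, with a median of -0.92 (camera adjusted p = 3.74e-15; adjusted p = 0.29 with an estimated correlation). Fetal growth genes fell in 15 of 20 cases and rose in 2, or 15 and 3 adjusted over the list alone (camera adjusted p = 6.12e-05; adjusted p = 0.19 with an estimated correlation). Chromatin regulators fell in 23 of 39 cases and rose in 4, or 23 and 6 adjusted over the list alone (camera adjusted p = 0.00661; adjusted p = 0.29 with an estimated correlation). Wnt pathway genes fell in 17 of 40 cases and rose in 5, or 18 and 5 adjusted over the list alone (camera adjusted p = 0.0268; adjusted p = 0.582 with an estimated correlation). Stress genes rose in 14 of 28 cases and fell in 6, or 14 and 7 adjusted over the list alone (camera adjusted p = 0.00661; adjusted p = 0.665 with an estimated correlation). Hair cell synapse and channel genes rose in 12 of 27 cases and fell in 6, the same adjusted over the list alone (camera adjusted p = 0.0292; adjusted p = 0.582 with an estimated correlation). Over 18 alternatives with the preset correlation, 8 of these 11 lists kept their call throughout. The hair cell synapse list lost it under 2, with adjusted p from 0.0149 to 0.139, and the SoxC and interferon lists under 1 each, at adjusted p = 0.0761 and 0.0641. The bundle list (adjusted p = 0.0742) was called higher under 2 alternatives, the Notch list (0.0637) lower under 2 and cholesterol synthesis (0.246) higher under 1. Their adjusted p ran from 0.0185 to 0.204, from 0.0296 to 0.106 and from 0.0233 to 0.837. In total 2323 genes were higher and 2878 lower at P9 than P0, with 461 and 419 changed at least 2-fold.

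Whether the intervals before and after P0 differed was tested directly with the interval contrast. The intervals cover different numbers of days, so the contrast compares the total change of each. Ribosomal protein genes had a more negative change after P0 in 56 of 74 cases and a more positive one in 0, or 71 and 0 adjusted over the list alone (camera adjusted p = 2.21e-21; adjusted p = 0.55 with an estimated correlation). On the log2(RPKM + 1) scale, cell cycle genes had a more positive change after P0 in 13 of 55 cases and a more negative one in 4, or 19 and 4 adjusted over the list alone (camera adjusted p = 1.51e-04; adjusted p = 0.561 with an estimated correlation). This depends on the pseudocount: with 0.1 the counts were 4 and 4 and the list was not called (camera adjusted p = 0.591), and its median went from 0.41 to -0.09. With a mean of at least 10 RPKM it was not called either (median -0.16, adjusted p = 0.353). In ratios of mean RPKM, 2 of the 13, Top2a and Mcm5, fell more after P0 than before it, so whether cell cycle genes fell less after P0 is not settled. Hair cell regulators had a more negative change after P0 in 9 of 18 cases and a more positive one in 0, or 11 and 0 adjusted over the list alone (camera adjusted p = 1.49e-05; adjusted p = 0.473 with an estimated correlation). The interval contrast of Atoh1 was -1.75 ± 0.17. Sox4 and Sox11 had interval contrasts of -1.10 ± 0.16 and -1.03 ± 0.23 (adjusted p = 0.00104 and 0.0121), and Sox12 one of -0.53 ± 0.18 (adjusted p = 0.067). Stress genes had the more positive change after P0 in 13 of 28 cases and the more negative in 0, or 14 and 0 adjusted over the list alone (camera adjusted p = 3.07e-08; adjusted p = 0.473 with an estimated correlation). Interferon genes had the more positive change after P0 in 8 of 14 cases and the more negative in 1, or 10 and 1 adjusted over the list alone (camera adjusted p = 1.44e-04; adjusted p = 0.174 with an estimated correlation). Dark cell markers had it in 4 of 12 cases against 0, the same adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.561 with an estimated correlation). The change after P0 was more negative for 12 of 40 Wnt pathway genes and more positive for 0, or 14 and 0 adjusted over the list alone (camera adjusted p = 6.79e-04; adjusted p = 0.473 with an estimated correlation). As a list the SoxC genes were called too, with 2 of 3 more negative and 0 more positive, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0144; adjusted p = 0.473 with an estimated correlation). Fetal growth genes were more negative in 9 of 20 cases and more positive in 2, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.044; adjusted p = 0.473 with an estimated correlation). Cartilage and bone genes were more negative in 4 of 10 cases and more positive in 1, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.039; adjusted p = 0.633 with an estimated correlation). Of the 2 muscle genes 1 was more negative and 0 more positive, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.039; adjusted p = 0.473 with an estimated correlation). Over 17 alternatives with the preset correlation, only the ribosomal, hair cell regulator, Wnt and stress lists, 4 of 11, kept their call throughout. Fetal growth lost it under 8, cartilage and bone under 5 and muscle under 3, with adjusted p up to 0.335, 0.0895 and 0.366. The SoxC, dark cell and interferon lists lost it under 1 each, at adjusted p = 0.0649, 0.207 and 0.194. Other lists gained a call under some alternatives. Without P0 replicate 2 the bundle, hair cell synapse and Notch lists were called more negative after P0, at adjusted p = 0.00111, 0.00727 and 0.0438 against 0.142, 0.105 and 0.105 with all libraries. Oxidative phosphorylation and mesenchyme were then called more positive, at 2.26e-04 and 0.0346 against 0.476 and 0.131. The synapse and mesenchyme lists were called under 1 further alternative each. The neuron list reached 0.0129 with a mean of at least 10 RPKM, against 0.117, and the otolithic list 0.0492 without P0 replicate 3, against 0.142. The highest adjusted p of the bundle, synapse, Notch, oxidative phosphorylation, mesenchyme, neuron and otolithic lists were 0.881, 0.45, 0.216, 0.889, 0.359, 0.228 and 0.536. In all, 729 genes changed more positively after P0 and 984 more negatively, 1713 together, a total that fell to 978 without P0 replicate 3.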

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

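The test of opposite directions described here was chosen after the data were seen, and the test of the difference between intervals was planned. The change differed between the interval before P0 and the interval after it for 1713 genes by the interval contrast. Within these, 165 genes rose to P0 and then fell, and 70 fell and then rose, each called in both intervals. Simulated data with no change gave 0 such genes in either direction, and simulated data with 200 genes changed at P0 gave 3 among the unchanged genes. The first made 0 calls in each interval, and the second changed far fewer genes than the real data, where 28.9% and 51.5% were called. The adjusted threshold was therefore stricter in the simulations, and neither gives a chance value for the real counts. Genes called up in both intervals numbered 887 and down in both 797, where independent lists of the same sizes would share 358 and 388. For the opposite directions such lists would share 444 and 313, more than the 165 and 70 found. Both intervals use the P0 libraries, and with 3 of them they could not be divided, so part of these counts may come from shared chance values. Without P0 replicate 3 the counts were 92 and 34. Without E17.5 replicate 2 they were 97 and 37, the first count was 96 without E17.5 replicate 3, and quantile normalization gave 108 for the second. With a minimum mean of 10 RPKM they were 99 and 46, and with a log2 fold change of at least 1 they were 3 and 2.

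Among the genes named by the fixed rule, 4 changed direction at P0. Oc90 went from 1367 ± 60.2 to 1800 ± 170 and then 91.2 ± 3.17 RPKM (interval contrast -4.68 ± 0.19). The hair cell factors Pou4f3 and Gfi1 were higher at P0 than at either other age, at 119 ± 3.54 and 103 ± 4.58 RPKM, with interval contrasts of -0.94 ± 0.16 and -1.03 ± 0.14. Tfrc, the transferrin receptor, was lowest at P0 at 6.32 ± 0.493 RPKM (interval contrast 1.08 ± 0.16).

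For the interval contrast, 5 of 100 assignments of the 9 libraries to the ages, the real one included, called at least 1713 genes, and the highest of the others called 5712. By this count chance is not excluded. The median assignment called 0 genes, and each of the 4 others that reached the real value placed all 3 libraries of P9, or all 3 of E17.5, in the middle position. Assignments that call several times the real count point to a structure of the samples, here their grouping by age.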

How the results depend on the processing

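Results that kept their direction and call under every alternative are not listed singly, and calls of lists that were lost or gained in contrasts other than P9 against E17.5 are given with those contrasts above. Of the alternative values for counts, 177 stayed within 1.5 times the main count and 30 did not, and of those for named genes 2901 kept their call, 15 lost it, all under the fold minimum, and 3 gained it. No list called for P9 against E17.5 and no called named gene changed direction. In the other contrasts only the cell cycle list did, for the interval contrast, from a median of 0.41 to -0.09 with a pseudocount of 0.1 and -0.16 with a mean of at least 10 RPKM. For named genes a pseudocount of 5 moved 56 called fold changes over 1.5-fold and one of 0.1 moved 8. With a minimum mean of 10 RPKM, which leaves 6448 genes, the counts higher and lower were 1964 and 2312 for P9 against E17.5, 995 and 760 for P0 against E17.5, and 1481 and 1792 for P9 against P0, with 1057 for the interval contrast and 54 of the transcription factors. There the SoxC, neuron and interferon lists were no longer called, with medians of -0.95, 0.13 and 1.25. With a log2 fold change of at least 1 the counts were 945 and 773, 129 and 100, and 461 and 419, with 604 for the interval contrast. These follow from fewer genes and from the stricter rule. Removing single libraries gave 820 to 1564 genes lower at P0 than E17.5 and 978 to 1895 for the interval contrast. Without P9 replicate 3, 16 lists were called instead of 11.

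With an estimated correlation 0 lists were called, with medians as before, at -1.16 for SoxC, 0.64 for the bundle, 0.66 for the hair cell synapse, 0.65 for the otolithic list, -2.30 for the cell cycle, -1.50 for fetal growth, -0.50 for chromatin, 0.59 for neurons, 1.04 for dark cells, 1.70 for interferon and -1.04 for ribosomal proteins. With fry, which does not compare a list with other genes, 23 lists were called. Other causes were not tested.

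The labels number the libraries 1 to 3 at each age. Libraries with the same number had correlated deviations of -0.372 to 0.275, and not every library correlated best with its own number, so the numbers were not taken to pair them. With the number as a block, 3103 genes were higher and 3692 lower at P9 than E17.5, and 1665 differed between intervals, against 3116, 3692 and 1713 without. A fit to recovered reads was not run because the gene lengths behind the values are not given. Genes under 5 RPKM throughout were not measured.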

Other observations

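The tests of heat shock genes and of the share of sensory epithelium, its repeat on members limited by level, the removal of a length and GC trend, and the count of length-matched genes with repeats were chosen only after results had been seen. The other tests of ribosomal protein genes were chosen after their fall was seen but before the results of those tests. Other lists had members called in both directions from E17.5 to P9, and camera called none of them. Epithelial junction genes split into 16 higher and 15 lower of 43, or 16 and 16 adjusted over the list alone (camera adjusted p = 0.746, with a median of 0.10, a mean of -0.04 and a test direction of higher). The embryonic claudin gene Cldn6 fell from 296 ± 26.2 to 54.1 ± 10.6 RPKM and the cadherin gene Cdh3 from 47.3 ± 4.63 to 7.45 ± 1.16 RPKM, and Gja1 and Myh10 fell by 2.24 ± 0.11 and 1.46 ± 0.08. Basement membrane genes split into 13 higher and 12 lower of 29, or the same adjusted over the list alone (camera adjusted p = 0.9, with a median of 0.15, a mean of -0.07, a camera direction of higher and a fry direction of lower). Fbln1, Fn1 and Itga6 fell by 3.61 ± 0.10, 3.29 ± 0.10 and 2.67 ± 0.10, and the protease inhibitor gene Timp1 rose by 2.82 ± 0.11. Singled out after their values were seen, the collagen gene Col4a1 went from 48.1 to 11.2 RPKM and Col4a2 fell by 1.31, while Col4a3 and Col4a4 rose by 2.54 and 2.40.

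Of 24 planar polarity genes, 6 rose and 9 fell, the same adjusted over the list alone (camera adjusted p = 0.768). Prickle2 and Celsr2 rose by 1.21 ± 0.09 and 0.99 ± 0.10, and Fzd3 and Fjx1 fell by 1.48 ± 0.11 and 1.56 ± 0.16. Cholesterol synthesis genes rose in 11 of 24 cases and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.0751), with a list call without P9 replicate 3 at adjusted p = 0.0124, the lowest of 18 alternatives with the preset correlation that reached 0.255. Pmvk, Hsd17b7, Srebf2 and Fdft1 rose by 1.04 ± 0.09, 1.35 ± 0.13, 0.82 ± 0.10 and 1.23 ± 0.16, and exons of Fdft1 overlap those of Ctsb on the opposite strand. Cartilage and bone genes split into 5 higher and 4 lower of 10, the same adjusted over the list alone (camera adjusted p = 0.533). Among them Col2a1 fell from 254 ± 19.5 to 30.6 ± 6.57 RPKM, Alpl fell by 1.89 ± 0.19, Chad rose by 3.11 ± 0.11 and Col11a2 rose by 1.17 ± 0.12.

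Ribosomal protein genes had a median change of -0.996 on the log2 scale from P0 to P9. They were compared with the 130 other genes closest in level among those of similar length, with no limit on the difference in level. Each counted once, 43 of the 130 were called lower. These genes had a median change of -0.042 (quartiles -0.44 and 0.26), but their median length was 1399.5 bp against 1076.5 bp. Counted as often as they were matched, they had a median length of 1054 bp and a median change of -0.06 (quartiles -0.61 and 0.24). This argues against annotated length as the whole cause. Lengths were those of the longest annotated transcript, which may exceed the expressed one, so an effect of short expressed transcripts was not tested. After removal of a trend on the length and GC content of the longest annotated transcript, the median was -0.96 (quartiles -1.06 and -0.78). Of the 73 called genes, 72 stayed called after quantile normalization. These values argue against a trend on that length and GC content, and against library scaling, as the whole cause. An effect of age stays open as a hypothesis, as does any difference in library preparation between ages, since the labels give no batch, and splitting of reads with pseudogenes was not tested.

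Heat shock genes rose from P0 to P9 in 6 of 6 cases, with a median of 2.16 on the log2 scale. Reads shared within the Hspa1a and Hspa1b pair are argued against as the whole cause, because Hspb1, Hsph1 and Dnajb1 rose by a median of 1.40. Handling of the P9 tissue might raise immediate early genes together. Of 22 such genes 8 rose, 6 fell and 8 were not called, with a median of 0.16, so handling and age cannot be told apart from these values.

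A smaller share of sensory epithelium in the P9 samples might raise markers of every other cell type alike. Median log2 fold changes were 0.98 for Schwann cell, 0.89 for melanocyte, 0.59 for neuron and 0.23 for cartilage and bone genes. The median was -0.23 for the 4 erythroid genes, of which 1 was called higher and 0 lower. It was -1.30 for the 2 muscle genes, of which 1 rose and 1 fell. Cd68, the only gene measured of 34 leukocyte markers, rose by 1.20. Dark cell markers rose by a median of 1.04 (quartiles 0.54 and 2.13). Mesenchyme markers had a median of -0.78 (quartiles -1.81 and 0.43) and 10 of 16 fell, but camera did not call them (adjusted p = 0.163). Among these lists only mesenchyme had more members called lower than higher, so the values do not settle a general dilution. The quartiles of the dark cell and mesenchyme lists no longer separated under limits on level, which themselves depend on the change. The mesenchyme median was 1.39 (quartiles -0.89 and 3.02) over 4 genes with a mean of at least 10 RPKM. It was -0.19 (quartiles -2.05 and 2.22) over 7 that reached 10 RPKM at the age where they were highest. Of the 12 dark cell markers 4 are also in another list, and the hair cells and supporting cells of the epithelium also express sodium pump genes. A general dilution, more dark cell tissue in the P9 samples, or higher expression of these genes within the epithelium, stays open.

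The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Each split was fitted to the 6 libraries of the 2 ages alone, so the real counts differ from those of the fit to all 9 libraries. For P9 against E17.5, 1 of the 10 splits, the real one, called 6859 genes and the highest other 0. For P0 against E17.5, 1 split reached the real 3323 and the highest other was 2, and for P9 against P0, 1 split reached the real 4619 and the highest other was 0.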
